A study of Solanum lycopersicum with 2 samples.

How the data were processed

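Messenger RNA of tomato (Solanum lycopersicum, cultivar Moneymaker) was profiled by MACE, a 3'-end tag sequencing method in which each polyadenylated transcript is meant to give a single read from near its 3' end, so that read numbers do not scale with transcript length. There was 1 library from anthers, the pollen-bearing organs of the flower, and 1 from young leaves. Both came from glasshouse plants 8 weeks old that received no treatment. The anthers were of different developmental stages, per the labels' protocols. Each library was placed in its group by its tissue label.

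Each deposited file lists, per gene, an identifier of the Solyc type, the chromosome (0 to 12), a strand written as wat or cri, estimated counts of reads (called all hits), the library's mapped reads, a scaled value and the height of the highest read peak, per the file headers. The estimated counts deposited by the authors were whole within 1e-06 reads for most genes. Counts were fractional for 20.8% of the genes in the anther file and 19.5% in the leaf file. Fractions are taken here as reads shared between several places, which the headers do not state. The scaled value is called transcripts per 1000000 per the file headers, but it equalled the estimated count divided by the library's mapped reads times 1000000 within 1.45e-08 in the anther file and 3.42e-08 in the leaf file. It is therefore called RPM (reads per 1000000 mapped reads) here, and the authors applied no length correction in it. The peak height is a signal value deposited by the authors whose computation the headers do not give. FastQC was named, without a version, per the submitters' processing notes. The aligner, the counting tool, the genome build and the annotation release are not given in the sources used here.

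The files do not pair the identifiers with gene names or descriptions. Of the 25923 identifiers, 0 matched an identifier, symbol, synonym or accession in a RefSeq gene table of assembly SLM_r2.1 with 41476 genes. The 27 gene lists fixed before the data were examined (7 of them of ribosome biogenesis factors, the others of ribosomal proteins, translation, photosynthesis, pollen, pollen wall, cell wall, lipid transfer, floral MADS-box, meiosis, histone, cyclin, heat stress, wound defence, respiration, trichome and reference genes) are defined by words in gene descriptions. So 0 of them could be filled, and the comparison of ribosome biogenesis factors and of their co-orthologs was not analysed here. By the rule fixed before the data were examined, at most 2 identifiers per direction are named, those with the largest log2 ratios among genes with a mean of at least 100 RPM.

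With 1 library per tissue there is no replicate check, no test was run across the tissues and no p-value is given. All differences are differences between these 2 libraries. A gene listed in only 1 file was taken as 0 in the other. Genes with a mean of the 2 values of at least 1 RPM were compared by log2((anther RPM + 1) / (leaf RPM + 1)), which understates the change of low genes, and a log2 ratio of at least 1 in either direction is called at least 2-fold. For fold changes of single genes, counts were rounded and a 95% exact conditional Poisson interval (Clopper-Pearson) of the ratio was computed. Such intervals cover counting error only, and the reads carry no molecular identifiers that are named in the sources, so reads need not be independent molecules. At these depths 1 read corresponds to 0.0806 RPM in the anther library and 0.0867 RPM in the leaf library, and the limit that a count of 0 allows (3 reads) corresponds to 0.242 and 0.260 RPM. Shares of genes carry Wilson 95% intervals, which treat genes as independent.

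Medians of gene sets were placed among 10000 random lists of the same size matched on mean level in 20 bins. Genes were ordered by chromosome and by the number in the identifier, which in this naming scheme increases along the chromosome, and consecutive tested genes with numbers at most 20 apart were called neighbours (chromosome 0 left out). Their log2 ratios were correlated and compared with 1000 shuffles within the 20 level bins, and intervals came from 1000 bootstrap resamples of pairs (2000 for differences). These resamples treat pairs as independent, though consecutive pairs can share a gene, so the intervals may be too narrow. The computations were tested on simulated data: with Poisson reads for 17122 genes of the anther and leaf comparison, the 2-fold rule called 30% of 50 genes simulated at 2-fold, 94% at 3-fold, 96% at 4-fold and 100% at 8-fold, and 0% of the unchanged genes. The simulated reads held counting error only, so 0% is not the rate of false calls between single libraries of these tissues. A neighbour correlation simulated at 0.2 was recovered as 0.194.

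Alternatives fixed in advance were pseudocounts of 0.1 and 5, no filter, a mean of at least 10 RPM, a rescaling that sets the median ratio to 1, a rescaling without the 50 genes of highest mean, and a log2 ratio threshold of 2. TMM scaling (edgeR 4.0.16 in R 4.3.3, on rounded counts, normalization factors only), scaling to reads on listed genes, restriction to genes listed in both files or to genes with whole-number reads, and other neighbour distances were added after seeing the data, as were thresholds of 4-fold and 10-fold under each scaling, pseudocount and gene filter. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.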

Results

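MACE profiles were compared between anthers and young leaves of tomato, with 1 library per tissue. The series addresses the expression of ribosome biogenesis factor orthologs, proteins that process ribosomal RNA and assemble ribosomal subunits, in a vegetative and a reproductive tissue. These factors were not analysed here, because the files give identifiers without gene names. The comparison below therefore covers all listed genes, described by level, chromosome and identifier. The anther library held 12411606 mapped reads, of which 69.2% lay on 24538 listed genes. The leaf library held 11534512 mapped reads, of which 72.5% lay on 22893 listed genes. The median listed gene had 55 reads in the anther library and 51 reads in the leaf library. All values are single measurements without replicates.

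The anther library held transcripts of more genes than the leaf library. Of 25923 genes listed in either library, 21508 were listed in both, 3030 in the anther library alone and 1385 in the leaf library alone. Most genes of the last 2 groups were near the detection limit, with a median of 2 reads in the anther-only group and 1 read in the leaf-only group. The anther-only group contained 592 genes with at least 10 reads and 72 genes with at least 100 reads. The leaf-only group contained 85 and 4 such genes. The highest count was 524 reads among anther-only genes and 364 reads among leaf-only genes. Gene models whose identifier carries the suffix 1 after the point made up 75.3% of the anther-only genes and 76.8% of the leaf-only genes, against 34.8% of the genes listed in both libraries. A level of at least 1 RPM was reached by 16802 genes in the anther library and 15710 genes in the leaf library.

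Gene levels differed widely between the tissues. Among 17137 genes with a mean of at least 1 RPM, 3690 (21.5%) were at least 2-fold higher in the anther library, 3006 (17.5%) were at least 2-fold higher in the leaf library and 10441 (60.9%) lay between. Differences of large size were more often towards the anther: 677 genes were at least 10-fold higher in the anther library and 315 in the leaf library. Across genes, which are not independent replicates, the levels of the 2 libraries had a Pearson r of 0.68 and a Spearman rho of 0.68. The 95% counting interval lay wholly beyond 2-fold for 83.4% of the genes at least 2-fold higher in each library. The interval is of the ratio without the pseudocount, and the genes were picked from the same counts by the smaller ratio with it. A high share is therefore partly built in. These intervals compare the 2 libraries and hold no variation between plants.

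The balance between the tissues depended on the level of the genes. Among the 7848 genes with a mean of 1 to 10 RPM, 24.3% were at least 2-fold higher in the anther library and 15.4% in the leaf library. Among the 8041 genes of 10 to 100 RPM the shares were 17.8% and 18.1%. Of the 1178 genes of 100 to 1000 RPM, 340 were at least 2-fold higher in the anther library and 295 in the leaf library, and 46.1% lay between. In the 70 genes of 1000 RPM or more, 14 were at least 2-fold higher in the anther library and 45 in the leaf library, with a median log2 ratio of -2.49. Over all tested genes 55.1% of the genes at least 2-fold apart were higher in the anther library (95% interval 53.9% to 56.3%). With TMM scaling this share was 50.3% and the median log2 ratio of all tested genes moved from 0.15 to 0.03, a shift of -0.12. At a mean of at least 10 RPM 1782 genes were higher in the anther library and 1799 in the leaf library, a share of 49.8% (48.1% to 51.4%).

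**Figure D1:**
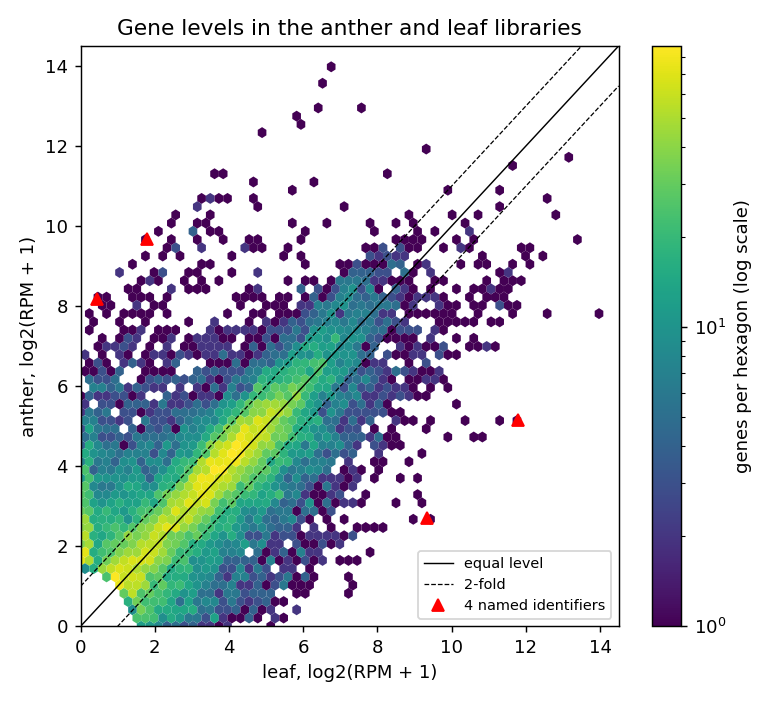
Level of each of the 17137 genes with a mean of at least 1 RPM in the leaf library (horizontal axis) and the anther library (vertical axis), both as log2(RPM + 1), coloured by the number of genes per hexagon on a log scale. The solid line marks equal levels, the dashed lines mark 2-fold differences, and the triangles mark the 4 identifiers given with values in the text, of which 2 lie far above and 2 far below the line.

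The genes farthest apart differed by 2 orders of magnitude. Among genes with a mean of at least 100 RPM, the 2 highest log2 ratios were those of Solyc06g069220.1 and Solyc02g078050.2. The log2 ratios hold the pseudocount, but the fold values of single genes and their intervals do not. The order by fold can therefore differ from the order by log2 ratio. Solyc06g069220.1 on chromosome 6 had 813 RPM in the anther library and 2.43 RPM in the leaf library (10092 and 28 reads). Its log2 ratio was 7.89, and its level was 335-fold higher in the anther library with a counting interval of 232 to 504. Solyc02g078050.2 on chromosome 2 had 287 RPM in the anther library and 0.347 RPM in the leaf library, the latter from 4 reads, which gave a log2 ratio of 7.74 and an 827-fold higher level with a counting interval of 323 to 3036. The 2 lowest log2 ratios were those of Solyc04g007790.2 and Solyc08g082120.2. Solyc04g007790.2 on chromosome 4 had 34.4 RPM in the anther library and 3528 RPM in the leaf library. Its log2 ratio was -6.64, and its level was 103-fold higher in the leaf library with a counting interval of 93.2 to 113. Solyc08g082120.2 on chromosome 8 had 5.56 RPM in the anther library and 649 RPM in the leaf library, a log2 ratio of -6.63 and a 117-fold higher level in the leaf library with a counting interval of 92.2 to 150, and part of its leaf reads were fractional. The order within each pair turned with a pseudocount of 0.1 (8.33 and 9.33, -6.68 and -6.84), with TMM scaling (7.89 and 8.00, -6.79 and -6.83) and with scaling to the reads on listed genes (8.08 and 8.13, -6.58 and -6.63), and that of the anther pair also without the 50 genes of highest mean (8.04 and 8.24). In the whole class of 1248 genes with a mean of at least 100 RPM, 354 were at least 2-fold higher in the anther library and 340 in the leaf library, and 117 and 66 of these were at least 10-fold apart.

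The most abundant transcripts of the tissues were largely different genes. Of the 100 most abundant genes of each library, 21 were shared, and 13 when the 50 genes of highest mean were left out. The 100 most abundant anther genes held 24.5% of the anther reads on listed genes and 10.4% of the leaf reads, and 69 of them were at least 2-fold and 54 at least 10-fold higher in the anther library. The 100 most abundant leaf genes held 31.6% of the leaf reads and 6.68% of the anther reads, and 86 of them were at least 2-fold and 27 at least 10-fold higher in the leaf library. Genes picked for a high level in a library are tilted towards that library by the choice itself. The 5 most abundant anther genes lay on chromosomes 1, 1, 7, 9 and 6 and were 152-fold, 142-fold, 100-fold, 39.6-fold and 120-fold higher in the anther library. The 5 most abundant leaf genes lay on chromosomes 2, 7, 9, 7 and 10 and were 76.6-fold, 13.8-fold, 2.61-fold, 6.04-fold and 10.4-fold higher in the leaf library. These 10 fold values are ratios of RPM without the pseudocount. Each of these 10 genes had fractional counts, as did 61 of the 100 most abundant genes in either library, so their levels depend on how shared reads were divided among similar genes.

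Leaf transcripts were concentrated in fewer genes. The most abundant gene took 2.33% of the anther reads and 2.21% of the leaf reads, and the 10 most abundant genes took 10.5% and 10.1%. The 50 most abundant genes took 19.0% of the anther reads and 23.9% of the leaf reads. A total of 689 genes held 50% of the anther reads, against 480 genes in the leaf library. The effective number of genes, the exponential of the Shannon entropy of the read shares, was 3690 in the anther library and 2875 in the leaf library.

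**Figure D2:**
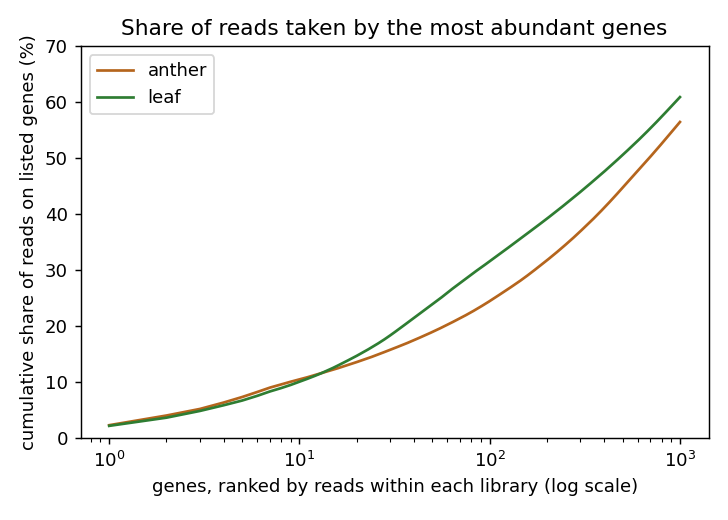
Cumulative share of the reads on listed genes (vertical axis, %) taken by genes ranked by reads within each library (horizontal axis, log scale), with 1 line for anther and 1 for leaf. The lines run together over the 10 most abundant genes (10.5% and 10.1%) and part beyond, to 24.5% and 31.6% at 100 genes.

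The chromosomes differed modestly in the balance of the tissues. In the main setting chromosome 6 stood farthest towards the anther, with 25.3% of its 1564 tested genes at least 2-fold higher in the anther library and 15.5% in the leaf library. Its median log2 ratio of 0.273 lay above the central 95% of random lists matched on level (0.0846 to 0.2005). Among genes with whole-number reads in both libraries chromosome 3 lay ahead of it, with medians 0.079 and 0.055 above that of all genes. Chromosome 3 (median 0.239 against 0.088 to 0.195) and chromosome 1 (0.193 against 0.091 to 0.187) also lay above the range of their own random lists. In the main setting chromosome 8 stood farthest towards the leaf, with 20.2% of its 1282 tested genes higher in the anther library and 20.4% in the leaf library, and a median of 0.04 at the 0.13 percentile of its random lists. At a mean of at least 10 RPM chromosomes 5 and 10 lay farther towards the leaf, with medians 0.089 and 0.088 below that of all genes against 0.083 for chromosome 8. Chromosomes 5, 9 and 10 also lay below the 2.5th percentile of theirs, with medians of 0.07, 0.07 and 0.08. In all, 7 of the 13 chromosome numbers lay outside the central 95%, where 0.65 would by chance if genes were independent. Neighbouring genes were correlated, so the random lists were narrower than lists of linked genes would be. By reads, chromosome 1 took 21.1% of the anther reads and 14.6% of the leaf reads, and its 2 most abundant anther genes alone took 2.33% and 1.72% of the anther reads.

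**Figure D3:**
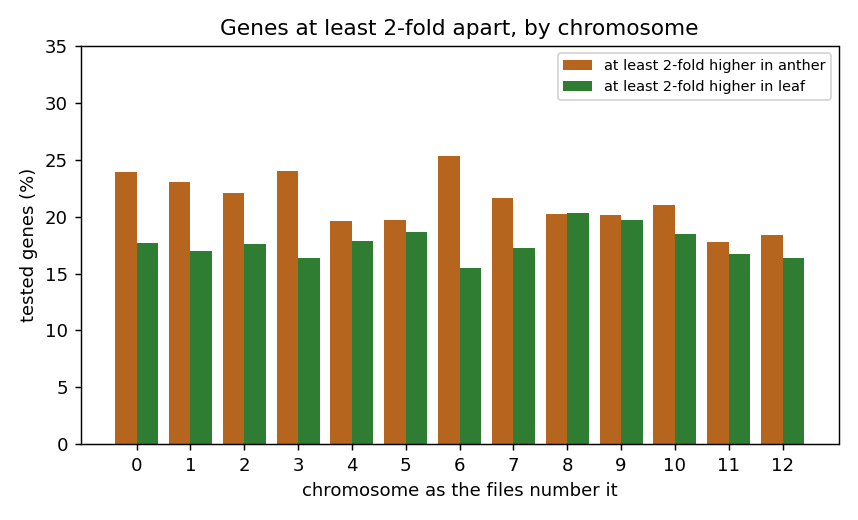
Share of tested genes (vertical axis, %) at least 2-fold higher in the anther library (brown bars) or the leaf library (green bars) for each chromosome number in the files (horizontal axis; 0 is the number the files use beside 1 to 12). The bars of chromosome 6 are farthest apart (25.3% and 15.5%) and those of chromosome 8 are about level (20.2% and 20.4%).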

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

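The reads outside the listed genes and the peak heights were not part of the comparison of gene levels, in which the mapped reads entered as the denominator of RPM, and 3 signals in them stood out. Of the mapped reads, 30.8% in the anther library and 27.5% in the leaf library did not lie on listed genes.

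The highest peak was higher than the gene's own read number for 356 genes in the anther file and 325 genes in the leaf file, with a median of 3 reads in both files, and 85 and 68 of these genes had fractional counts.

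Peak height was divided by the gene's reads for 7827 genes with at least 100 reads in both libraries and a peak no higher than the reads. This ratio, called the peak share here, had a median of 25.1% in each library. The headers do not state that the peak counts the gene's own reads, so it need not be a true share of them. Across these genes, which are not independent replicates, the peak share had a Pearson r of 0.91 and a Spearman rho of 0.78 between the tissues. The peak share differed by over 20 percentage points in 22 genes, 13 with the higher share in the anther library and 9 in the leaf library. Of these 22 genes 12 had fractional counts, against 29.2% of all 7827, and 8 were at least 2-fold apart in level, against 27.2% of all.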

How the results depend on the processing

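Of the 3690 genes at least 2-fold higher in the anther library and the 3006 in the leaf library, a pseudocount of 5 left 2261 and 1970, a mean of at least 10 RPM left 1782 and 1799, and a log2 ratio threshold of 2 left 1710 and 1228, each by its construction. The 8 other settings kept both counts within 1.5 times. The share of these genes that were higher in the anther library, 55.1%, became 53.4% with a pseudocount of 5, 51.8% with the median ratio set to 1, 58.2% at a log2 ratio threshold of 2, 50.3% with TMM scaling, 58.1% with scaling to the reads on listed genes and 53.2% among genes listed in both libraries. It fell to 49.8%, and so changed sides, at a mean of at least 10 RPM, where fewer low genes are tested, and to 49.2% when the threshold was 2 as well. With TMM scaling and a threshold of 2 it was 54.9%. The 4 named identifiers kept their direction under each setting that held them, but a pseudocount of 5 moved Solyc06g069220.1 from 7.89 to 6.78, Solyc02g078050.2 from 7.74 to 5.77, Solyc04g007790.2 from -6.64 to -6.49 and Solyc08g082120.2 from -6.63 to -5.95, and TMM scaling moved Solyc04g007790.2 to -6.79. The median log2 ratio of all tested genes, 0.148, ranged from 0.030 with TMM scaling to 0.214 with scaling to the reads on listed genes. The 21 genes shared by the 100 most abundant of each library became 13 without the 50 genes of highest mean and 16 with whole-number genes only. The 7 chromosome medians named in the text kept their direction relative to all genes in each of 10 settings, but with no filter those of chromosomes 1, 3, 5, 6, 8, 9 and 10 shrank from 0.045, 0.091, -0.083, 0.125, -0.104, -0.078 and -0.065 to 0.016, 0.016, -0.039, 0.070, -0.039, -0.039 and -0.012, and with whole-number genes only those of chromosomes 5 and 6 fell to -0.055 and 0.055. At a mean of at least 10 RPM chromosome 1 had 0.019 and chromosome 9 -0.048, with a pseudocount of 5 chromosomes 5, 8 and 9 had -0.053, -0.064 and -0.050, and chromosome 10 had -0.035 with TMM scaling and -0.028 without the 50 genes of highest mean. The correlation of neighbouring genes, 0.133, stayed above the shuffled values in each of 12 settings (0.077 to 0.151). The alternatives planned for the ribosome biogenesis factors, the other gene lists and the co-orthologs were not run, since 0 of the lists could be filled. No replicate could be left out and no paired analysis was possible because each tissue had 1 library. Depth limits genes near 1 RPM, which rest on about 12.4 reads in the anther library and 11.5 in the leaf library.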

Other observations

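Genes at least 2-fold apart in the same direction formed runs along the identifier order more often than in the shuffles. The runs were counted over all tested genes and not over whole-number genes alone. Reads divided among similar neighbouring genes could add to such runs, and how much they add was not tested. Runs of at least 4 neighbouring tested genes that were all at least 2-fold higher in the anther library occurred 46 times, against a median of 16 and a maximum of 31 in 1000 shuffles. Runs of that length towards the leaf occurred 33 times, against a median of 8 and a maximum of 18. The longest leaf run held 10 genes on chromosome 2, which together had 11550 RPM in the leaf library and 1694 RPM in the anther library, a 6.82-fold difference, and 9 of the 10 had fractional counts in at least 1 library. No shuffle gave a leaf run that long. A run of 6 genes on chromosome 9 had 6750 RPM in the anther library and 130 RPM in the leaf library, 52.0-fold apart. All 6 lay on the same strand and had fractional counts. A run of 6 genes on chromosome 3 had 787 RPM in the anther library and 6.68 RPM in the leaf library, 118-fold apart as a sum, with log2 ratios of single genes from 1.16 to 7.25, and 2 of its genes had fractional counts. The other runs of 6 genes were smaller in level: 323 RPM in the anther library and 106 RPM in the leaf library on chromosome 7 (3.05-fold), and 3.99 RPM in the anther library and 64.3 RPM in the leaf library on chromosome 5 (16.1-fold higher in the leaf library). Runs of 6 anther-higher genes were not rare by themselves, since 436 of the 1000 shuffles held a run at least as long.

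The tests of neighbouring genes were set down before their results were seen, except those of overlapping 3' ends in same-strand pairs and in opposite-strand pairs, which replaced a planned one afterwards, and those of the number of listed genes and of the anther excess only after those patterns had been seen. Over 13706 pairs of neighbours the log2 ratios had a correlation of 0.133 (95% bootstrap interval 0.114 to 0.152), against -0.016 to 0.017 in the shuffles. Reads shared between near-identical copies are argued against as the whole cause, if whole-number counts hold no shared reads, which the headers do not state. The 7965 pairs with whole-number reads still had a correlation of 0.086, above the shuffled range of -0.022 to 0.022. Shared reads may account for part of the difference. Copies lying in the same direction are a candidate explanation, as a hypothesis: same-strand pairs exceeded opposite-strand pairs by 0.112 (0.074 to 0.151), and by 0.048 (0.003 to 0.095) among whole-number pairs. The interval of the whole-number pairs only just excludes no difference, and it may be too narrow because consecutive pairs can share a gene. Reads of overlapping 3' ends counted for both neighbours are argued against as the whole cause. The 7046 same-strand pairs, whose 3' ends do not face each other, had a correlation of 0.183 (0.154 to 0.213). Their shuffled range was -0.024 to 0.023. Among the 4011 same-strand pairs with whole-number reads the correlation was lower, 0.109 (0.076 to 0.140), but above the shuffled range of -0.031 to 0.030. Overlapping 3' ends stay open for opposite-strand pairs. Pairs with a cri gene before a wat gene had a correlation of 0.118 and pairs in the other order 0.029, within the shuffled range. Which strand wat is was not stated. The pairs whose 3' ends face each other therefore cannot be told apart from those whose 3' ends point away. The difference between the orders was 0.089 (0.034 to 0.143).

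More genes were listed in the anther library than in the leaf library. A difference in library depth is argued against. The anther reads were thinned 100 times to the leaf library's reads on listed genes, and genes with at least 1 rounded read were counted. The anther library held 23784 such genes before thinning and a mean of 23734.5 (SD 7.04) after it, against 22201 in the leaf library. After thinning by the ratio of mapped reads 23645 remained. The difference between the tissues, including the range of anther stages collected, and a difference between single libraries stay open and were not tested.

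More genes were at least 2-fold higher in the anther library than in the leaf library at 1 RPM or more. A few genes taking most of the counts were tested as the 50 genes of highest mean, and these 50 are argued against as the whole cause. Without them the share higher in the anther library was 54.6% (53.5% to 55.7%). That setting also scaled to the reads on the remaining listed genes. Under such scaling with all listed genes kept the share was 58.1%. The 50 genes may therefore account for part of the excess. Abundant genes beyond these 50 stay open as a cause. The 100 most abundant genes of each library took 24.5% of the anther reads and 31.6% of the leaf reads on listed genes. A difference in library depth could not be judged as a cause of this excess. The share was 55.1% before thinning and 55.0% after the anther reads were thinned to the leaf library's reads on listed genes. That depth gap was small, as thinning took only 2.66% of the anther reads on listed genes, and RPM already divides by the mapped reads. So slight a thinning was taken to decide nothing, by a rule added after the share was seen. No conclusion on depth is drawn from it. The scaling to all mapped reads stays open for the 2-fold excess, as the other scalings disagreed: the share was 50.3% (49.2% to 51.5%) with TMM scaling, 51.8% (50.6% to 53.0%) with the median ratio set to 1 and 58.1% (56.99% to 59.24%) with scaling to the reads on listed genes. This was first judged by TMM scaling alone, and by all the scalings only after their shares had been seen. For the excess at 4-fold or more, 1710 genes against 1228, the scaling is argued against as the whole cause. The share was 58.2% in the main setting and 54.9% (53.2% to 56.6%) with TMM scaling, 1824 genes against 1498. The interval of the share stayed above 50% with each other scaling. Scaling may still account for part of this excess. The 4-fold excess rested on low genes, however, as the share was 49.2% (46.9% to 51.6%) at a mean of at least 10 RPM and 52.6% (49.9% to 55.2%), 740 genes against 668, with a pseudocount of 5. At 10-fold or more 677 genes against 315 were higher in the anther library, 751 against 422 with TMM scaling and 513 against 278 at a mean of at least 10 RPM. The difference between the tissues and a difference between single libraries stay open and were not tested.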
